A study of Canis lupus familiaris and Rattus norvegicus and Macaca fascicularis with 674 samples.

How the data were processed

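RNA sequencing of tissues from beagle dogs, cynomolgus monkeys and Wistar Han rats gave 674 libraries in 138 tissue groups. Per the labels' protocols, total RNA was isolated with RNeasy kits and libraries were prepared with a stranded mRNA kit (TruSeq), a kind of kit that selects polyadenylated RNA. Per the submitters' processing notes, base calls were converted with bcl2fastq and expression was quantified with Salmon 1.10.1. The genome builds and annotations are not given in the sources used here. The deposited values are estimated counts per gene that the authors made with Salmon, and in the table they stand as whole numbers. Of 1137 deposited count values of at least 1000000, 1118 are multiples of 10, so the largest values carry fewer digits. Salmon shares reads between near-identical genes by a model, so values of paralogs and pseudogenes are uncertain.

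Each row of the deposited table is a library, matched to its sample by its library number. The table also holds 1509 libraries that match no sample here, and these were not used in any step. Groups follow the labels, which give species, tissue, batch and library number. They give no replicate number and do not tie a library to an animal or a sex. The series text describes males and females and some pooling, so p-values measure the spread between these libraries only. The monkey libraries belong to several batches. Tests between monkey tissues used the largest batch (cynomap_2.0), in which both tissues of every pair are found, and an alternative added the other monkey batches with batch as a term for heart, brain and kidney.

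Rows of the table name genes by Ensembl identifiers, 30941 in dog, 38352 in monkey and 30257 in rat, and the files do not pair them with names. The name table at hand covers the dog (43286 genes), and 0 of the 30941 dog identifiers matched it. The symbol-based lists, the tests of a difference between species and the match of tissues by gene symbol that had been planned before the data were examined could therefore not be made. They were replaced, after the data were seen, by organ lists made from the libraries themselves and by a comparison of tissue arrangements within each species. The rule for named genes took, per species and direction, the gene with the largest absolute log2 fold change among those past the threshold, with a mean of at least 10 CPM in the higher tissue and every library of the higher tissue above every library of the lower one. As written, that rule left out Ensembl identifiers; it was applied to them here because there were no symbols. At most 2 genes per direction are printed for a pair of tissues, chosen from those the rule gave.

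Counts were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), using TMM normalization, the filterByExpr filter with the tissue as group, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Log2 fold changes are coded as the first tissue named minus the second, and the SE is the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM on the total count of the library. Where a tissue had no count, the fold is a lower bound against 3 counts over the libraries of that tissue, and where it had 1 to 3 counts, the ratio has a 95% binomial interval (Clopper-Pearson) for counting error only. Numbers of genes at 16-fold or more, and medians of lists, were computed with such genes at their bound. The bound changed 1 median of a list past the threshold, that of intestine genes in rat liver against kidney (4.33 at the bound, 4.45 as fitted; camera adjusted p = 0.00943, and adjusted p = 0.782 with an estimated correlation). The sources used here name no molecular identifiers that would mark PCR duplicates, so intervals and floors cover counting error only.

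A list for an organ held genes with a median of at least 10 CPM in a tissue of that organ and at least 4-fold above all other organs, among the libraries outside the organs compared, with at most 100 and at least 10 genes. For ileum against colon, lists of the upper small intestine (duodenum and jejunum, in the rat jejunum alone) and of the cecum held genes at least 4-fold apart between those parts. For the brain, a white matter list held genes of the corpus callosum (in the rat, of the cervical spinal cord) at least 2-fold above the brain regions not compared. Lists were tested with camera (limma) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a pair of tissues, and again with the correlation estimated for each list. Scores of a list are means of log2(CPM + 1). Organ-enriched genes used mean CPM of groups with at least 2 libraries. In the monkey, these genes and the organ lists drew on the largest batch and on the batch of the cultured endothelial cells (ec_map_1.0_cyno). For the arrangement of tissues, Spearman's rho between mean profiles of the 16 matched tissues was turned into distances, and the distance matrices of 2 species were compared by Pearson's r and Spearman's rho with 100000 permutations of the tissues of 1 species. Each library was also correlated with the mean of every tissue group, on log2(CPM + 1), leaving itself out of its own group. Replicates were compared for identity by chi-square over genes, and every pair differed by more than sampling noise, so no library was counted together with another.

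The steps were tested on simulated counts with 200 genes changed by 1.5-, 2- or 4-fold in each pair of tissues. At 4-fold, 53.0%, 69.7% and 89.4% of changed genes were recovered for atrium against ventricle in dog, monkey and rat, and 21.2%, 25.8% and 77.3% for ileum against colon. The share of false calls among calls was highest for ileum against colon in the monkey (15%, 3 calls) and for cerebellum against cortex in the monkey (10.6%, 13 calls). These counts of changed genes are small, so the shares are imprecise. With 200 genes changed, the adjusted threshold is also stricter than in pairs where many more genes differ, so recovery there may be higher.

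The planned tests, the named-gene rule and the alternatives for them were fixed before the data were examined. The alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a stricter filter (at least 1 CPM in every library of a tissue and at least 10 counts), leaving out each library in turn, and other thresholds for organ-enriched genes. Chosen after the data were seen were 6 further pairs of tissues with all their alternatives, the organ lists with theirs (the estimated correlation among them), the tissue arrangements with their other distances, the comparison of each library with every group, and fits without the libraries whose expression was closest to another organ. For organ-enriched genes and tissue arrangements, a group whose libraries were all of that kind kept them. The rat prostate, with libraries 220 and 261, was such a group. Other divisions of the libraries, up to 100 per pair of tissues, were tested in the same way. Data handling used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R with matrixStats 1.5.0 and version 1.17.8 of data.table. The monkey library with 3224 counts was left out of all comparisons, and groups with 1 library entered none.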

Results

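Gene expression was measured by RNA sequencing in 674 libraries from 138 tissue groups of 3 species: beagle dogs (248 libraries, 55 groups), cynomolgus monkeys (200 libraries, 32 groups) and Wistar Han rats (226 libraries, 51 groups). A group is 1 tissue label of 1 species, and its libraries serve as replicates. Some tissues, such as the monkey cornea (labelled Cornea and EyeCornea), stand in more than 1 group. Group sizes ran from 1 library (6 groups) to 8 (17 groups), and 35 groups had 6 libraries. Total counts per library, in units of 1000000, ranged from 19.0 to 64.1 in dogs (median 38.3), from 27.3 to 69.3 in the largest monkey batch (median 42.6) and from 23.5 to 41.2 in rats (median 37.4). One monkey amygdala library from a smaller batch held 3224 counts and entered no comparison. Genes are given by their Ensembl identifiers, because the files do not pair these with names, so the text describes tissues and groups of genes and prints few identifiers. The labels do not tie libraries to single animals, and pooling is mentioned, so p-values measure only the spread between these libraries.

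The series maps expression across the tissues of species used in nonclinical research. The comparisons ask which genes separate related tissues within a species, which genes mark an organ, and how alike the arrangement of tissues is between species. Lists of genes marking an organ were built from libraries outside the tissues compared. They were chosen after the data were seen and come from the same series, although not from the libraries they were tested on. Levels are counts per 1000000 counts (CPM), given as mean ± SD, and log2 fold changes as the value ± SE of the fit.

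Atrium and ventricle, the receiving and pumping chambers of the heart, differed in every species, and most of the large differences lay on the atrial side. Of the genes called with at least a 16-fold difference, 83 were higher in the dog atrium and 56 in its ventricle, 119 and 18 in the monkey, and 134 and 39 in the rat. The rat gene ENSRNOG00000000465 stood at 73.7 ± 13.7 CPM in the atrium (n = 6) and had no count in the left ventricle (n = 5), which is at least 4788-fold higher against a floor of 3 counts over the group. The dog gene ENSCAFG00845025035 stood at 605 ± 103 CPM in the left atrium (n = 5) and 0.526 ± 0.0700 CPM in the left ventricle (n = 2), a log2 fold change of 9.99 ± 0.38 (edgeR adjusted p = 1.8e-05). On the ventricular side, the monkey gene ENSMFAG00000036782 stood at 8064 ± 1891 CPM in the ventricle (n = 6) against 16.0 ± 19.6 CPM in the atrium (n = 6), a log2 fold change of -10.27 ± 0.96 (edgeR adjusted p = 1.2e-05). The rat gene ENSRNOG00000030848 stood at 8663 ± 575 CPM in the ventricle against 89.0 ± 165 CPM in the atrium (log2 fold change -7.10 ± 1.36, edgeR adjusted p = 0.00173). Single libraries carried both atrial means, monkey library 931 with 55.6 CPM (the others 4.41 to 12.0) and rat library 267 with 419 CPM (the others 2.13 to 90.9).

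Genes that mark other organs moved with the monkey atrium. Of 17 artery genes tested, 8 rose in the atrium, 1 rose in the ventricle and 8 did not pass (median log2 fold change 1.21; camera adjusted p = 1.16e-06, and adjusted p = 0.0159 with an estimated correlation). Of 38 liver genes, 15 rose in the atrium and 3 in the ventricle (median 1.04; adjusted p = 9.36e-07, and 0.0204 as the adjusted p with an estimated correlation). Of 49 genes of peripheral nerve and ganglion, 19 rose in the atrium and 4 in the ventricle (median 0.89; adjusted p = 0.000510), and the adjusted p was 0.342 with an estimated correlation. The list with the smallest adjusted p was that of B cells in the dog (0.256) and that of peripheral nerve and ganglion in the rat (0.126), where 12 of 33 genes rose in the atrium. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 1629 of 17330 genes in the dog (756 higher in the atrium, 873 in the ventricle), 3514 of 18428 in the monkey (1930 and 1584) and 4858 of 15530 in the rat (2519 and 2339). The dog count fell to 453 without ventricle replicate 2 and to 971 without ventricle replicate 1, fits in which the lone ventricle library is assumed to vary like the atrial ones, and DESeq2 called 2800.

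**Figure D1:**
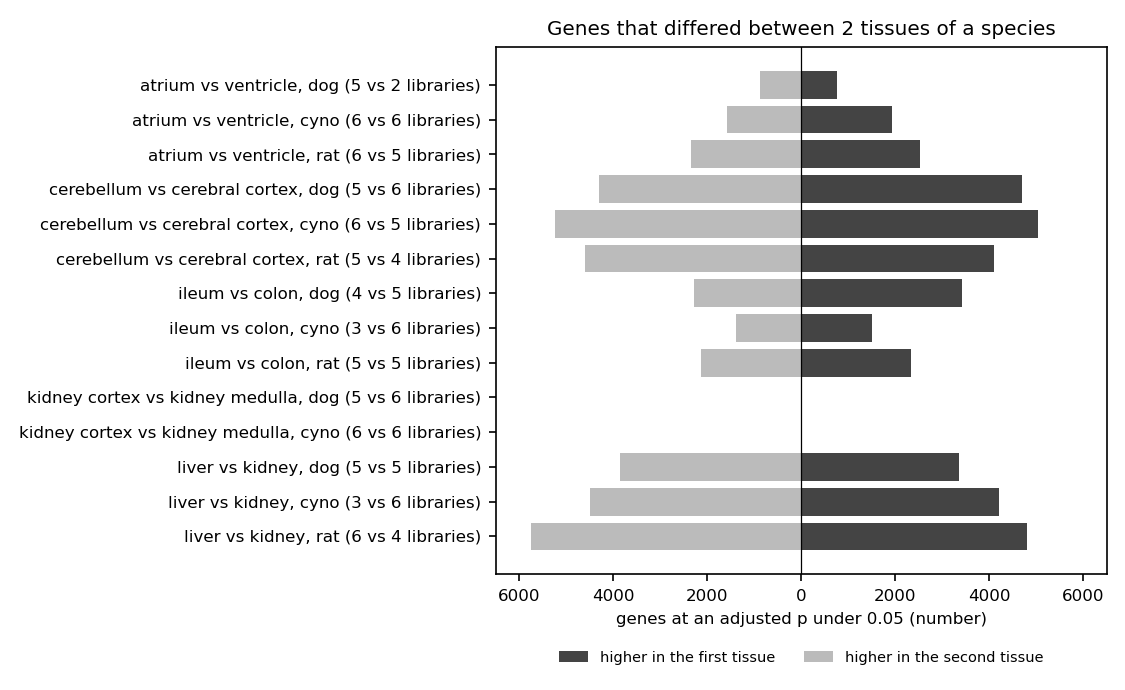
Bars give the number of genes at an adjusted p under 0.05 (edgeR) for each planned pair of tissues, with genes higher in the first tissue named drawn to the right and those higher in the second drawn to the left. The longest bar to the left was that of the rat kidney against liver (5755 genes), and the longest to the right was that of the monkey cerebellum against cortex (5031). Kidney cortex against medulla had none in dog and monkey.

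Cerebellum and cerebral cortex, parts of the brain that coordinate movement and process sensory and motor information, were far apart in each species, and the large differences lay more on the cortical side. At 16-fold or more, 134 genes were higher in the dog cerebellum and 272 in its frontal cortex, 152 and 377 in the monkey, and 163 and 306 in the rat, whose cortex label names no lobe. In the dog, ENSCAFG00845008441 stood at 20.0 ± 9.80 CPM in the cerebellum (n = 5) with no count in the cortex (n = 6), at least 1569-fold higher. In the monkey, ENSMFAG00000049184 stood at 75.0 ± 12.4 CPM in the cerebellum (n = 6) against 2 counts over the 5 cortex libraries, a ratio of 7333 with a 95% counting interval of 2030 to 60555. On the cortical side, ENSRNOG00000009482 stood at 16.0 ± 5.88 CPM in the rat cortex (n = 4) with no count in the cerebellum (n = 5). That is at least 867-fold higher. ENSMFAG00000063338 stood at 10.4 ± 1.43 CPM in the monkey cortex with no count in the cerebellum, at least 738-fold higher.

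Genes of peripheral nerve and ganglion, which hold nerve cell bodies and their fibres outside the brain, rose mostly in the cortex. In the dog 49 of 88 rose in the cortex and 13 in the cerebellum (median log2 fold change -0.94; camera adjusted p = 1.69e-09), and the adjusted p was 0.571 with an estimated correlation. The monkey counts were 49 and 17 of 88 (median -0.76; adjusted p = 1.48e-06, and adjusted p = 0.0284 with an estimated correlation), and the rat counts were 38 and 12 of 77 (median -0.61; adjusted p = 0.0152, and adjusted p = 0.615 with an estimated correlation). Heart genes rose mainly in the cortex of the monkey (29 of 45, against 7 in the cerebellum; median -0.81; adjusted p = 0.0130, and adjusted p = 0.0284 with an estimated correlation) and of the rat (19 of 33, against 4; median -1.10; adjusted p = 0.0103, and adjusted p = 0.0969 with an estimated correlation). In the rat, 21 of 85 genes of the cervical spinal cord, taken there as tissue rich in white matter, rose in the cerebellum and 9 in the cortex (median 0.31; adjusted p = 0.00961, and adjusted p = 0.615 with an estimated correlation). Genes of the corpus callosum, the white matter list of the other species, did not pass in the monkey (51 of 95 rose in the cortex and 10 in the cerebellum; median -0.81; camera adjusted p = 0.113) or in the dog (2 of 41 and 6; median 0.38; camera adjusted p = 0.636). The edgeR test called 8987 of 18711 genes in the dog (4685 higher in the cerebellum, 4302 in the cortex), 10278 of 21826 in the monkey (5031 and 5247) and 8695 of 16596 in the rat (4095 and 4600).

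Ileum and colon, the last part of the small intestine and the large intestine, were separated by genes chosen as higher in neighbouring gut segments. Genes of the upper small intestine rose in the ileum for 59 of 87 in the dog, 83 of 97 in the monkey and 82 of 87 in the rat, and rose in the colon for 0, 1 and 2. Genes of the cecum rose in the colon for 44 of 100 in the dog, 70 of 99 in the monkey and 58 of 91 in the rat, and rose in the ileum for 0, 2 and 6. The dog lists come from groups with doubtful libraries. Duodenum libraries 813, 815 and 818 and jejunum libraries 824 and 826 were closest to fat or celiac ganglion, and cecum library 803 to celiac ganglion. Whether genes of those tissues entered the dog lists was not tested. The median log2 fold changes of the upper small intestine list were 3.06, 6.80 and 7.05 in the same order of species, with camera adjusted p of 2.05e-12, 2.03e-133 and 9.48e-186. With an estimated correlation the adjusted p was 0.323 in the dog, 0.000490 in the monkey and 0.000120 in the rat.

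For the cecum list the medians were -2.70 in the dog, -3.21 in the monkey and -2.25 in the rat (camera adjusted p = 1.32e-27, 1.48e-33 and 5.83e-33), and the adjusted p was 0.323, 0.145 and 0.0267 with an estimated correlation. Kidney genes rose in the rat ileum for 29 of 57 and in the colon for 9 (median 1.27; adjusted p = 1.20e-12, and adjusted p = 0.0267 with an estimated correlation). Liver genes rose in the rat ileum for 21 of 44 and in the colon for 3 (median 2.48; adjusted p = 1.20e-12), and the adjusted p was 0.139 with an estimated correlation. In the dog, genes of artery (12 of 22), heart (9 of 25) and peripheral nerve and ganglion (17 of 36) rose in the ileum, with medians of 2.05, 1.73 and 1.53 and adjusted p of 0.323, 0.323 and 0.316 with an estimated correlation. Every dog ileum library scored above every colon library on these lists, as mean log2(CPM + 1). The scores were 4.32 to 5.36 against at most 3.32 for artery, 2.47 to 2.82 against at most 1.97 for heart and 2.88 to 3.05 against at most 2.21 for nerve and ganglion. Ileum library 822 was closest to superior cervical ganglion (r = 0.956 across genes, against 0.794 with the other ileum libraries) and scored 0.795 on the cecum list, where the other ileum libraries scored 5.43 to 5.66. It also scored highest on the upper small intestine list (5.06, the other ileum libraries 3.30 to 3.72 and the colon at most 2.07), and the cause was not tested. Artery genes took the other direction in the monkey, where 7 of 18 rose in the colon (median -1.51), with an adjusted p of 0.145 with an estimated correlation.

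Among single genes, ENSRNOG00000029522 stood at 524 ± 121 CPM in the rat ileum (n = 5) and 0.0210 ± 0.0469 CPM in the mid colon (n = 5), a log2 fold change of 14.45 ± 0.57 (edgeR adjusted p = 2.0e-08). ENSMFAG00000036101 stood at 10.2 ± 12.5 CPM in the monkey ileum (n = 3) with no count in the colon (n = 6), at least 1045-fold higher. Library 883 carried that mean (24.6 CPM, with 1.76 and 4.17 CPM in the others). ENSRNOG00000050564 stood at 94.3 ± 26.1 CPM in the rat colon against 1 count over the ileum libraries, a ratio of 17419 with a 95% counting interval of 3126 to 688057. ENSMFAG00000033237 stood at 21.1 ± 11.1 CPM in the monkey colon with no count in the ileum, at least 767-fold higher. The edgeR test called 5693 of 18060 genes in the dog (3417 higher in the ileum, 2276 in the transverse colon), 2896 of 22209 in the monkey (1506 and 1390) and 4467 of 16731 in the rat (2330 and 2137). The dog count was 3978 to 6747 when 1 library was left out. On the first principal component of the dog libraries (48.6% of the variance), ileum library 822 lay at 240 and the other ileum libraries at 36.7 to 46.8. The monkey count depended on single libraries: it was 958 to 1045 without any of the 3 ileum libraries and 4467 without colon replicate 5, and DESeq2 called 4704, of which 41.3% were higher in the ileum.

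**Figure D2:**
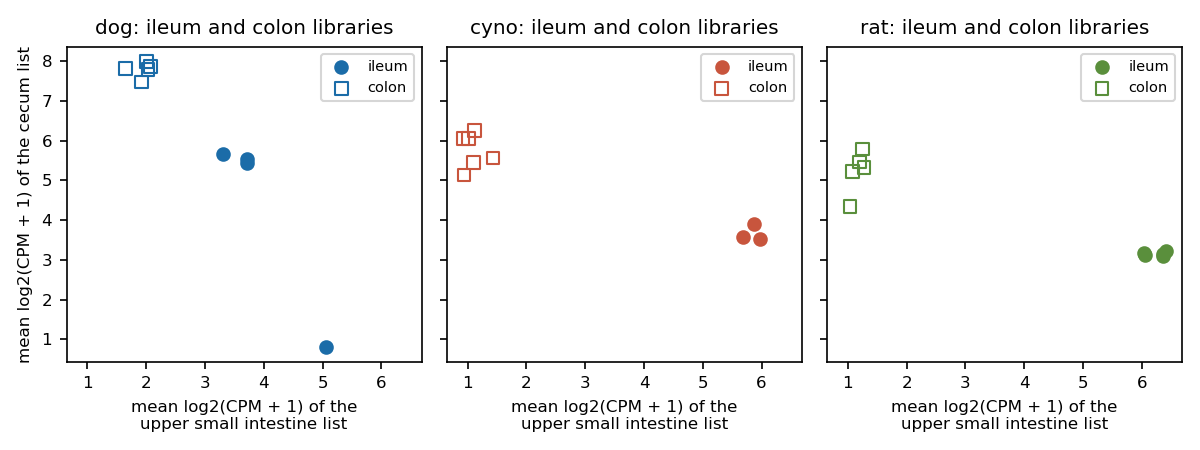
Each point is 1 library, placed by its mean log2(CPM + 1) over genes marking the upper small intestine (horizontal axis) and the cecum (vertical axis), with filled circles for ileum and open squares for colon. Ileum libraries lie to the right of and under the colon libraries in each species, and 1 dog ileum library lies far down at 0.795 on the cecum axis.

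Kidney cortex, which holds the glomeruli, and kidney medulla, which holds the loops of Henle and collecting ducts, had no gene called by the unpaired edgeR test in either species that has both. In the dog (5 cortex and 6 medulla libraries) edgeR called 0 of 17886 genes, with 414 genes (2.31%) at an unadjusted p under 0.05, while DESeq2 called 26. In the monkey (6 and 6 libraries) edgeR called 0 of 21310 genes, with 1508 genes (7.08%) at an unadjusted p under 0.05, while DESeq2 called 112, of which 101 were higher in the medulla. Libraries of the same part differed about as much as libraries of different parts. The root mean square log2 distance was 1.40 within and 1.37 between the parts in the dog, and 0.955 and 0.988 in the monkey. Monkey medulla libraries 921 and 923 correlated more with the mean of the cortex (r = 0.991 and 0.986, across genes) than with the other medulla libraries (0.975 and 0.970), and cortex library 905 more with the medulla (0.970 against 0.965).

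Groups of genes leaned to one part of the kidney without any member passing on its own. Liver genes had a median log2 fold change of 0.61 toward the cortex in the dog (51 genes; camera adjusted p = 0.000170, and adjusted p = 0.594 with an estimated correlation) and of 0.40 in the monkey (73 genes; adjusted p = 0.000299, and adjusted p = 0.372 with an estimated correlation). Artery genes had a median of -0.61, toward the medulla, in the monkey (16 genes; adjusted p = 0.000410, and adjusted p = 0.372 with an estimated correlation). The first principal component of the dog libraries (54.5% of the variance) set cortex library 899 and medulla libraries 913 and 914, at -132, -166 and -145, apart from the others at 25.4 to 78.8. In simulated data of the same size, 45.5% of genes changed 4-fold were recovered in the dog and 84.8% in the monkey. At 2-fold the shares were 4.48% and 31.3%, and at 1.5-fold 0% and 5.97%.

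Liver and kidney, the main organs of metabolism and of urinary excretion, had more genes called than any other planned pair in the rat. In the dog and the monkey they had fewer called than cerebellum and cortex, a count that also depends on the spread between libraries. The root mean square log2 distance between the tissues was larger for liver and kidney (2.40 in the dog and 2.22 in the monkey) than for cerebellum and cortex (1.58 and 1.40). At 16-fold or more, 548 genes were higher in the dog liver and 674 in its kidney cortex, 569 and 993 in the monkey, and 593 and 1088 in the rat, whose kidney samples hold both parts. The monkey gene ENSMFAG00000032395 stood at 4428 ± 1488 CPM in the liver (n = 3) and 0.0139 ± 0.0247 CPM in the kidney (n = 6), a log2 fold change of 18.89 ± 0.65 (edgeR adjusted p = 9.0e-09). The dog gene ENSCAFG00845014803 stood at 151 ± 39.1 CPM in the liver (n = 5) against 1 count over 5 kidney libraries, a ratio of 25837 with a 95% counting interval of 4637 to 1020520. The monkey gene ENSMFAG00000045632 stood at 5558 ± 1691 CPM in the kidney cortex with no count in the liver, at least 263989-fold higher. The dog gene ENSCAFG00845010351 stood at 40.4 ± 15.0 CPM in the kidney cortex with no count in the liver, at least 2988-fold higher.

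Gallbladder genes rose in the monkey liver for 87 of 98 and in the kidney for 4 (median log2 fold change 10.42; camera adjusted p = 2.53e-129, and adjusted p = 0.000252 with an estimated correlation). In the dog 27 of 51 rose in the liver and 9 in the kidney (median 3.48; adjusted p = 7.57e-09), and the adjusted p was 0.120 with an estimated correlation. The monkey list comes from gallbladder libraries in which liver genes took 10.8% ± 7.67 of counts (n = 6), as given below. Genes of bone marrow rose in the dog liver for 29 of 57 and in the kidney for 7 (median 1.95; adjusted p = 1.21e-05), and the adjusted p was 0.319 with an estimated correlation. In the monkey, 19 of 37 epididymis genes rose in the kidney and 5 in the liver (median -2.83; adjusted p = 2.55e-06, and adjusted p = 0.0429 with an estimated correlation). In the rat, 21 of 35 genes of peripheral nerve and ganglion rose in the kidney and 1 in the liver (median -1.22; adjusted p = 0.0133), and the adjusted p was 0.102 with an estimated correlation. The edgeR test called 7196 of 17271 genes in the dog (3345 higher in the liver, 3851 in the kidney), 8705 of 22210 in the monkey (4207 and 4498) and 10558 of 16459 in the rat (4803 and 5755).

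Liver genes took a larger share of counts in the monkey samples of gallbladder, the sac that stores bile, than in those of the dog. For this the liver genes were chosen without the gallbladder libraries, 185 in the dog and 202 in the monkey. They took 37.1% ± 1.96 of counts in the dog liver (n = 5) and 0.468% ± 0.0425 in the dog gallbladder (n = 6), close to the 0.504% ± 0.181 of the kidney cortex (n = 5). In the monkey they took 34.5% ± 3.11 in the liver (n = 3), 10.8% ± 7.67 in the gallbladder (n = 6, range 2.53% to 20.4%) and 0.573% ± 0.129 in the kidney cortex (n = 6). The levels in each monkey gallbladder library followed those of the liver across these genes (Spearman's rho at least 0.870). The share is therefore given for these samples and not for the organ. The difference between the species was not tested.

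**Figure D3:**
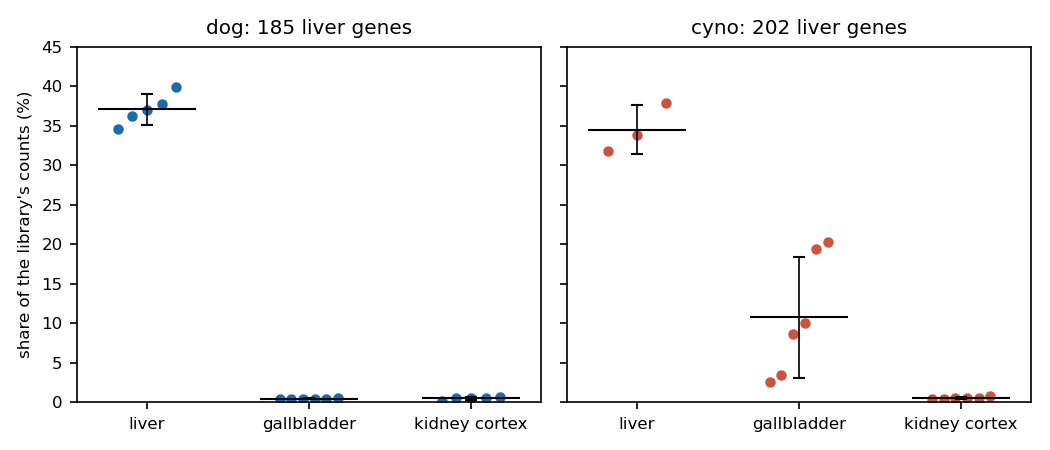
Each point is 1 library, with the percentage of its counts taken by liver genes on the vertical axis, and black lines give the mean and SD of a tissue. The 6 monkey gallbladder libraries spread from 2.53% to 20.4%, whereas the dog gallbladder libraries lie at 0.420% to 0.534%.

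Genes enriched in an organ were those at a mean of at least 10 CPM in a tissue of that organ and at least 4-fold above every tissue of the other organs. There were 2051 in the dog (51 groups, 16 organs), 2587 in the monkey (29 groups, 16 organs) and 2138 in the rat (50 groups, 29 organs). With all libraries, brain had the most in every species, with 556, 839 and 464 genes. Brain also had the most tissue groups (17 in the dog, 6 in the monkey and 6 in the rat). The rule takes the highest tissue of an organ, so an organ with more tissues has more chances to pass. Without prostate library 261 the rat testis had 1551 and the rat brain 463. After brain came eye (250 genes) and bone marrow (234) in the dog, cultured endothelial cells (440) and intestine (359) in the monkey, and the lymph node, spleen and thymus group (330) and intestine (247) in the rat. In the dog, isolated B cells had 192 such genes. The monkey endothelial cells are all from a batch of their own, so tissue and batch cannot be told apart for their 440 genes. The organs and the number of tissues differ between species, so these counts are not a test of a difference between them.

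The share of counts taken by enriched genes differed widely between organs. In the rat, 20 genes took 76.8% of counts in the mandibular salivary gland (2 libraries), 24 took 56.9% in the glandular stomach, 219 took 44.7% in the liver, 19 took 39.6% in the male accessory glands (29 genes without prostate library 261 and 53 without the libraries closest to another organ), 23 took 25.5% in the pituitary and 6 took 10.9% in the thyroid. Shares were lower in the epididymis (6.69%, 111 genes), the mammary gland (5.38%, 13) and the adrenal gland (3.22%, 16). In the dog, 183 genes took 37.0% of liver counts and 234 took 21.2% of bone marrow counts. The 40 genes enriched in the monkey liver took 2.30% of its counts when gallbladder was among the tissues compared. The single highest enriched gene, ENSRNOG00000014492 in the rat stomach, stood at 432180 ± 40801 CPM (n = 5), with 177 ± 277 CPM in the highest tissue of another organ, mesenteric lymph node. The count for the rat testis was 3 genes, because prostate library 261 carried testis genes. Without that library 1551 genes marked the testis, and they took 35.0% of testis counts, 34.2% of library 261 and 0.449% of the other prostate library, while the rat total became 3687.

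**Figure D4:**
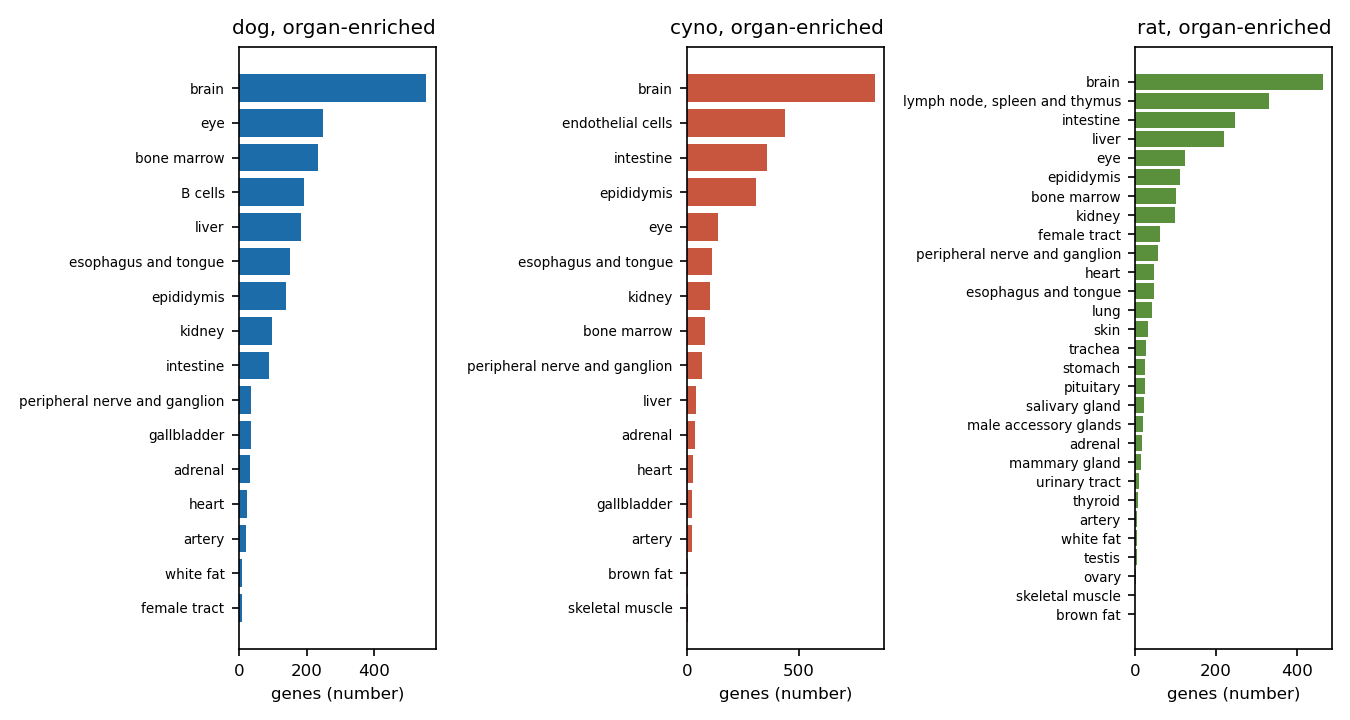
Bars give the number of genes enriched in each organ, at a mean of at least 10 CPM and at least 4-fold above all other organs, with 1 panel per species and its own horizontal scale. With all libraries kept, as drawn, brain leads in each panel, with 556, 839 and 464 genes in dog, monkey and rat. Without prostate library 261, which is not drawn, the rat testis would lead with 1551.

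The arrangement of 16 tissues matched by their labels in all 3 species was compared through the correlations between tissue means within each species. This needs no match of genes between species. The 16 include the cornea, whose match is uncertain. Its rat libraries carry the tissue name Retina in the deposited table, and 5 of 6 correlated more with brain than with tongue, esophagus and skin. No setting left the cornea out. Across the 120 pairs of tissues, the distances of monkey and rat had a Pearson r of 0.882 and a Spearman rho of 0.830, those of dog and rat 0.80 and 0.714, and those of dog and monkey 0.736 and 0.603. In 100000 permutations of the tissues the p for each r was 1e-05, the smallest these permutations can give, and the Benjamini-Hochberg adjusted p over the 3 pairs of species was 1e-05. The permutation p for rho was 3e-05 for dog and monkey and 1e-05 for the others. Without the 2 tissues farthest from the median distance, r was 0.811, 0.756 and 0.741 in the same order. For monkey and rat these tissues were cerebellum and cerebral cortex, so that fit is the same as the one without the brain tissues. For the other pairs of species they were bone marrow and cerebral cortex. Tissue pairs share tissues and are not independent, and the permutations keep that structure. Without the brain tissues, which form a cluster of their own, r was 0.811, 0.737 and 0.525 and rho 0.742, 0.588 and 0.332 (permutation p for the last rho 0.0142). Without the libraries closest to another organ, r was 0.865, 0.844 and 0.817.

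The closest other tissue was shared by all 3 species for 8 of the 16 tissues. These were cecum and colon, cerebellum and cerebral cortex, ileum and jejunum, and atrium and ventricle, each closest to the other. Cecum and colon were the closest pair in the dog (rho 0.985) and the monkey (0.984), and in the rat they were as close as atrium and ventricle (both 0.971). Monkey and rat shared the closest tissue for 11 of 16, including the aorta for the adrenal gland (rho 0.894 in the monkey and 0.923 in the rat) and the kidney for the liver. The rat adrenal mean holds library 89, whose closest library is one of thoracic aorta. Without the libraries closest to another organ, the aorta was still closest to the rat adrenal gland (rho 0.886). All 3 species then shared the closest tissue for 11 of 16 (dog and monkey 11, dog and rat 12, monkey and rat 13). The esophagus was closest to a heart chamber in each species, to the ventricle in the dog and to the atrium in monkey and rat, although the dog sample was the muscular wall and the other labels name no layer.

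**Figure D5:**
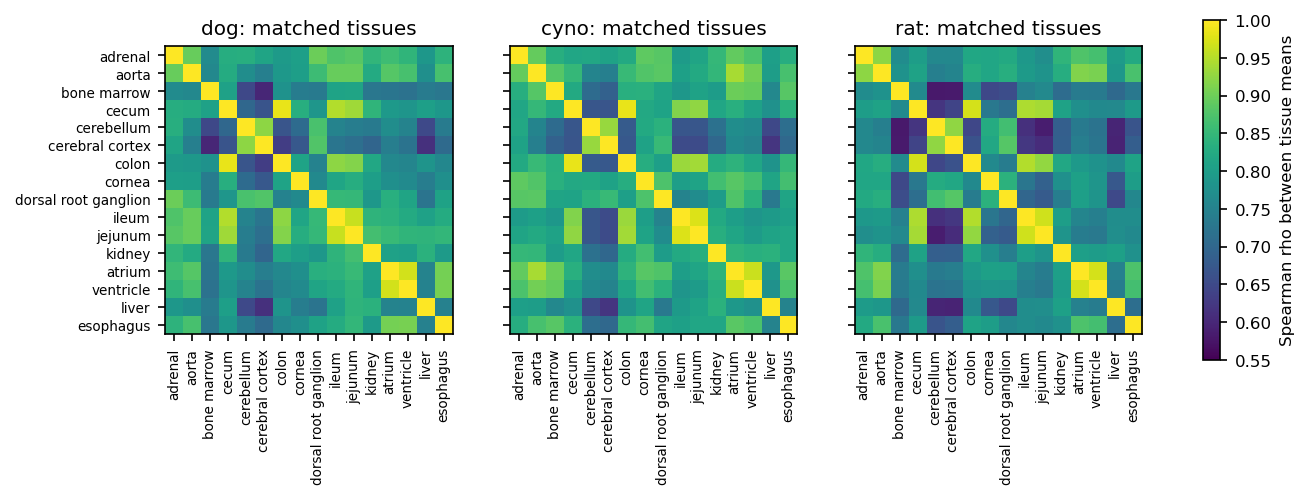
Colour gives Spearman's rho between the mean profiles of each pair of the 16 matched tissues, with 1 panel per species and the same tissue order on both axes. Bright blocks mark the pairs cecum and colon (0.971 to 0.985) and ileum and jejunum (0.963 to 0.977).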

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

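The tests of the 3 patterns weighed here were chosen after the correlations that pointed to those patterns had been seen, and what each test would show was written down before it was run. Libraries set apart by Dixon's test were looked for in 96 sets of values and found in 14. A set held the total counts, or the levels of 1 named gene, in 1 tissue group, so some groups entered more than once. Chance sets apart about 1 in 20 only where values are normally distributed. Some of the 14 were genes with counts in 1 library of a group, which the test sets apart by construction. The 14 of 96 can therefore not be set against that rate.

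Rat libraries 87, 88, 89, 90, 261 and 263, labelled inguinal skin, urinary bladder, adrenal gland, dorsal root ganglion, prostate and cornea, were closest to libraries of tongue, mandibular salivary gland, thoracic aorta, abdominal aorta, testis and salivary gland (r with the closest library 0.995, 0.983, 0.995, 0.995, 0.996 and 0.988). A mixture of the labelled tissue with the other organ would leave at least 5% of the labelled tissue's genes, but its median share was -0.00261%, -1.12%, -1.07%, -1.05%, -0.00385% and -0.224% in this order, with upper quartiles of 0.835% or less, where libraries of the labelled tissue had at least 62.1%. A wrong label needs a share under 5% and found it in 6 of 6, so these libraries may carry the label of another tissue, although for prostate the share rests on 1 other library (220), whose own label was not tested. An exchange between prostate library 220 and epididymis head library 217 would make library 220 correlate more than library 217 with the other 2 epididymis head libraries, but the difference was -0.0170 (0.767 against 0.784), where those 2 correlate at 0.980 with each other. Library 217 thus matched library 220 (r = 0.990) and not those 2, which leaves open whether only library 217 carries a wrong label. The step at which sample and label parted was not tested, and neither was a biological explanation.

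The 202 liver genes stood at 2.53% to 20.4% of counts in the 6 monkey gallbladder libraries. If they came from liver material in the sample, their levels would follow those of the liver, and Spearman's rho across these genes was at least 0.870 in every gallbladder library, against 0.297 to 0.370 in kidney cortex and 0.145 to 0.277 in aorta. Expression by the gallbladder itself would give ratios to liver that differ between genes by over 10-fold from the lower to the upper quartile, but the highest such ratio among the 6 libraries was 2.91. Liver material in the samples is therefore the likelier of these 2 explanations, and it would also enter the list of gallbladder genes in the monkey. Whether the amount differs between animals was not tested, since the labels do not name them.

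The rat libraries labelled cornea carry the tissue name Retina in the deposited table. If they held neural tissue, they would correlate more with brain than with tongue, esophagus and skin, and 5 of 6 did, by 0.0284 to 0.0680 in r. The exception was library 263 (-0.113), the library closest to salivary gland, and all 5 dog cornea libraries lay between -0.283 and -0.252. The prediction for neural tissue was met in the rat, but which part of the eye these libraries hold was not tested. In the monkey, where both names read cornea, differences ran from -0.146 to 0.0770, and what sets those libraries apart was not tested.

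Total counts set 1 library apart in each of several groups. The rat values were 33472769 in atrium library 267, 32809476 in visceral fat library 255, 23549248 in cerebellum library 64 and 34606878 in ileum library 254, each the lowest of its group. The dog values were 47421224 in frontal cortex library 323 and 51537237 in kidney medulla library 913, each the highest, and monkey inferior parietal library 886 had 34039193, the lowest of its group.

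Single genes named in the text had 1 library apart on the log2(CPM + 1) scale. ENSMFAG00000036782 was at 5.82 in monkey atrium library 931, above a group median of 3.34, and ENSRNOG00000030848 was at 13.24 in rat ventricle library 228 (median 13.04). Groups otherwise at 0 held 1 library with counts: rat colon library 60 at 0.14 for ENSRNOG00000029522, rat ileum library 62 at 0.0384 for ENSRNOG00000050564 and dog kidney cortex library 903 at 0.0322 for ENSCAFG00845014803. ENSRNOG00000030688 was at 2.00 in tibial nerve library 187 (median 5.45), and ENSRNOG00000067803 at 2.87 in thoracic aorta library 82 (median 5.19).

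For some organ lists, every library of 1 tissue scored above every library of the other in 1 species and under it in another, although the difference between species was not tested. In cerebellum against cortex, the median log2 fold change of heart genes was 0.35 in the dog, -0.81 in the monkey and -1.10 in the rat. The dog list did not pass (camera adjusted p = 0.809; 8 genes rose in the cerebellum and 9 in the cortex). In ileum against colon, artery genes had a median of 2.05 in the dog and -1.51 in the monkey, and gallbladder genes had -1.43 in the dog and 0.49 in the monkey. With an estimated correlation none of these 4 passed (camera adjusted p = 0.323 and 0.145 for artery, 0.55 and 0.340 for gallbladder). The dog ileum libraries scored from 1.19 to 4.36 on the gallbladder list.

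Groups with a single library entered no comparison, but each held counts for many genes. Dog reproductive fat also stands in another group, labelled AdiposeWhiteReproductive. There were 21088 genes with a count in dog reproductive fat (library 1), 22043 in dog adrenal medulla (library 17), 21020 in dog brown fat (library 395), 18881 in the dog culture labelled AoEC (library 462), 22163 in the monkey culture labelled LMVEC (library 441) and 18045 in rat eye lens (library 144).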

How the results depend on the processing

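The organ lists, all settings of the 6 pairs of tissues added later, the settings of the tissue arrangements and the fits without libraries closest to another organ were chosen after the data were seen, and the other settings were planned. Across settings, 255 of 291 counts of called genes stayed within 1.5 times the reported count and 36 did not, 485 values of named genes kept their direction and their side of the threshold, 246 counts of lists past the threshold stayed and 45 moved, 26 counts of organ-enriched genes stayed and 5 moved, and 15 correlations of tissue arrangements kept their sign and their side of the threshold. These 15 hold 1 monkey and rat fit under 2 names, since its tissues farthest from the median distance were the brain tissues. No named gene changed sign, which was likely from the start. The named genes were chosen from these same libraries as the largest differences without overlap between tissues. A setting whose filter removed a named gene gave no value for it. In 22 of 291 fits, spread over 9 of the 20 pairs of tissues, the side with more called genes changed. For ileum against colon in the monkey, 41.3% of the genes called by DESeq2 were higher in the ileum, against 52.0% with edgeR. No paired analysis was possible because the labels give no replicate numbers that tie libraries of different tissues. The tests of a difference between species, the symbol lists and the match of tissues by symbol were not run, for lack of gene names. At these depths and this spread between libraries, small changes are often missed: of simulated 2-fold changes, 1.49% were recovered for atrium against ventricle in the dog, 0% for ileum against colon in the monkey and 65.7% for frontal against inferior parietal cortex in the monkey.

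With DESeq2 the counts were 2800 for atrium against ventricle in the dog, 4704 for ileum against colon in the monkey, 26 and 112 for kidney cortex against medulla in dog and monkey, 27 for motor against occipital cortex in the dog and 839 for frontal against inferior parietal cortex in the monkey. Leaving out 1 library at a time gave 453 to 1698 genes for atrium against ventricle in the dog, 958 to 4467 for ileum against colon in the monkey, 0 to 14 and 0 to 5 for the kidney parts in dog and monkey, 1051 to 4398 for sciatic against tibial nerve, 0 to 1 for motor against occipital cortex and 28 to 512 for frontal against inferior parietal cortex. The cause was not tested. At 8-fold in place of 4-fold, which is stricter by construction, organ-enriched genes numbered 1019 in dog, 1418 in monkey and 1202 in rat. For the rat they numbered 3687 without library 261 and 2111 to 3808 when a replicate was left out (3808 without replicate 2, to which library 261 belongs).

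With an estimated correlation, the number of lists past the threshold became 0 for cerebellum against cortex in dog (from 1) and rat (from 5), for ileum against colon in the dog (from 9), for the kidney parts in dog (from 3) and monkey (from 3), for liver against kidney in dog (from 5) and rat (from 2), for aorta (from 4), nerve (from 4), motor cortex (from 1) and fat (from 5). It became 1 for ileum against colon in the monkey (from 7), 3 in the rat (from 6), 2 for liver against kidney in the monkey (from 7) and 2 for the esophagus (from 6). Without a low-count filter it became 1 for dog heart (from 0), 5 for monkey heart (from 3), 2 for dog brain (from 1), 3 for rat brain (from 5), 1 for rat liver against kidney, 2 for aorta and 3 for motor cortex. The stricter filter gave 1 for dog heart, 2 for dog brain and 0 for motor cortex. With 1 library left out, the number of lists was 0 to 2 for dog heart, 1 to 2 for dog brain, 2 to 5 for monkey brain, 2 to 5 for the dog kidney parts, 1 to 2 for rat liver against kidney, 2 to 6 for aorta, 2 to 6 for nerve, 0 to 3 for motor cortex and 0 to 2 for frontal against parietal cortex. The cause of these moves was not tested.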

Other observations

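The pairs of tissues in the next paragraphs, the organ lists tested on them and the comparison of libraries with every group were chosen after the data were seen, whereas what other divisions of the libraries would show was written down before they were run.

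Mucosa and muscular wall of the dog esophagus were the most distinct of the added pairs, as 10394 of 17105 genes were called (5528 higher in the mucosa, 4866 in the muscularis; edgeR). Artery genes rose in the muscularis for 43 of 54 and in the mucosa for 5 (median log2 fold change -9.32; camera adjusted p = 4.85e-32, and adjusted p = 0.00280 with an estimated correlation). Heart genes rose in the muscularis for 26 of 34 and in the mucosa for 2 (median -3.36; adjusted p = 1.78e-09, and adjusted p = 0.00229 with an estimated correlation). Eye genes, from tissues that include the cornea, rose in the mucosa for 26 of 43 and in the muscularis for 8 (median 6.45; adjusted p = 1.14e-05), and the adjusted p was 0.194 with an estimated correlation. ENSCAFG00845018691 stood at 586 ± 110 CPM in the muscularis (SD, n = 5) against 2 counts over the 4 mucosa libraries, a ratio of 51102 with a 95% counting interval of 14146 to 421970. In rat fat, 9772 of 16109 genes separated brown fat, a heat-producing tissue, from visceral fat of the omentum (4942 higher in brown fat, 4830 in visceral fat). ENSRNOG00000003580 stood at 5804 ± 2043 CPM in brown fat (n = 6) and 0.846 ± 1.42 CPM in visceral fat (n = 4), a log2 fold change of 13.62 ± 1.46 (SE; edgeR adjusted p = 1.2e-05). Library 255 carried the visceral mean (2.96 CPM, the others at most 0.375). Genes of lymph node, spleen and thymus rose in visceral fat for 33 of 39 and in brown fat for 0 (median -1.74; camera adjusted p = 0.000466), and the adjusted p was 0.666 with an estimated correlation. Genes of the female tract rose in visceral fat for 13 of 20 and in brown fat for 1 (median -3.08; adjusted p = 1.73e-05), and the adjusted p was 0.168 with an estimated correlation.

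Along the rat aorta, 6594 of 16368 genes differed between the thoracic and the abdominal part (3509 and 3085 higher, 6 libraries each). Genes of peripheral nerve and ganglion rose in the abdominal part for 16 of 53 and in the thoracic part for 2 (median -1.40; camera adjusted p = 1.12e-05), and the adjusted p was 0.428 with an estimated correlation. Genes of brain (19 of 55, adjusted p = 0.000163), bone marrow (22 of 58, with 4 in the thoracic part, 0.0159) and epididymis (6 of 16, 0.0357) also rose in the abdominal part, with adjusted p of 0.424, 0.820 and 0.320 with an estimated correlation. Nerve and ganglion scores overlapped (1.43 to 3.70 thoracic, 3.38 to 4.67 abdominal). On the first principal component (50.4% of the variance) thoracic libraries 160 and 235, at -3.01 and 8.34, lay between the other thoracic libraries (90.7 to 118) and the abdominal ones (-95.4 to -34.0). ENSRNOG00000067803 stood at 32.8 ± 15.2 CPM in the thoracic and 0.463 ± 0.316 CPM in the abdominal aorta, a log2 fold change of 6.43 ± 0.61 (edgeR adjusted p = 1.1e-05). Sciatic and tibial nerve of the rat (6 libraries each) differed in 2172 of 16156 genes, of which 1808 were higher in the tibial nerve, and skeletal muscle genes rose in the tibial nerve for 6 of 13 and in the sciatic nerve for 0 (median -4.30; camera adjusted p = 7.16e-09, and adjusted p = 0.434 with an estimated correlation). Areas of the cerebral cortex were close: frontal and inferior parietal cortex of the monkey differed in 217 of 21769 genes (136 and 81), with 28 to 512 when 1 library was left out, and ENSMFAG00000028602 stood at 21.4 ± 6.90 CPM in inferior parietal cortex (n = 6) and 4.66 ± 1.79 CPM in frontal cortex (n = 5), a log2 fold change of -2.28 ± 0.27 (edgeR adjusted p = 0.00727). For motor and occipital cortex of the dog, edgeR called 0 of 18249 genes, with 806 (4.42%) at an unadjusted p under 0.05, and DESeq2 called 27.

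Other divisions of the same libraries were tested to see whether chance could give as many genes. For 15 pairs of tissues 1 division gave as many, the real one. These were atrium against ventricle in monkey (3514 genes, highest other 374) and rat (4858, 3926), cerebellum against cortex in dog (8987, 2), monkey (10278, 6403) and rat (8695, 5145), ileum against colon in dog (5693, 3), monkey (2896, 2037) and rat (4467, 133), liver against kidney in dog (7196, 1), monkey (8705, 129) and rat (10558, 2), and among the added pairs the aorta (6594, 2766), frontal against inferior parietal cortex (217, 2), the esophagus (10394, 3859) and rat fat (9772, 248). Chance is unlikely for these but not excluded, from 84 divisions for monkey ileum and liver and 100 for the others, with no adjustment over the pairs. Atrium against ventricle in the dog, with 2 ventricle libraries, was not tested in this way. The high counts of rat heart, monkey and rat brain, aorta and esophagus came from divisions that move 1 library or exchange a pair. For monkey ileum against colon, the 2037 genes came from setting colon libraries 449, 450 and 451 apart, which points to a structure of the samples. For the kidney parts and for motor against occipital cortex (highest other 2) the real count was 0, which all 100 divisions reach by construction, so this count tells nothing about chance there. The highest other counts of the kidney, 355 in the dog and 209 in the monkey, point to a structure of the samples: the dog division set libraries 899, 913, 914, 915 and 917 apart, and the monkey division exchanged cortex library 905 with medulla library 921.

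For sciatic against tibial nerve, 2 of 100 divisions gave as many genes, the real one (2172) and one that exchanged tibial library 187 with sciatic library 186 (3543). Chance is unlikely by this count but not excluded, since a division other than the real one gave more genes. Library 187 correlated more with sciatic nerve (r = 0.990 across genes) than with the other tibial libraries (0.914). Without it, tibial replicate 2, the count was 4398, and without tibial replicates 1, 3 or 6 it was 1069, 1051 and 1195. Without sciatic replicates 1, 4 or 5 it was 1356, 1246 and 1218.

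Each library was compared with every tissue group of its species. A match to the same tissue under another label, as for monkey cornea libraries 722 and 726, was not counted as the own group. The closest group was its own for 139 of 244 dog, 158 of 198 monkey and 206 of 225 rat libraries that had a group mate, and a group of another organ for 21 (8.61%), 4 (2.02%) and 15 (6.67%). Among the 21 dog libraries was library 12, labelled omental fat, which was closest to ileum (r = 0.910, against 0.742 with its own group). Monkey library 453, labelled cornea in a smaller batch, was closest to inferior parietal cortex (r = 0.970, against 0.683 with its own group). The closest pair of libraries in the dog joined motor and occipital cortex (r = 0.992, libraries 350 and 361), and in the monkey kidney cortex and medulla (r = 0.994, libraries 907 and 921).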
